A study of Homo sapiens with 8 samples.

How the data were processed

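Total RNA of U266/s, a human multiple myeloma cell line described as the parent, and of U266/LR7, its melphalan-resistant derivative, was measured on 8 one-colour Affymetrix arrays. The lines were crossed with melphalan (100 µM, a DNA-alkylating drug) and with inhibitors of the microRNAs miR-221 and miR-222 (100 nM), and RNA was taken 12 h after treatment, per the labels' protocols. Each of the 8 conditions has 1 array, so no condition was replicated. The labels disagree on the melphalan-alone arrays. Their transfection tag reads none, whereas the protocol text reads as if cells without inhibitors received a negative control oligonucleotide. The melphalan and inhibitor contrasts therefore hold this transfection difference as well if the tags are right.

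The deposited log2 values were made by the authors with Affymetrix Expression Console and RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes; versions and settings are not given in the sources used here. The table holds 33297 transcript clusters and 0 columns that belong to no sample. In the platform annotation, 19460 clusters have 1 gene symbol, 1754 have several and 12083 have none there. Of the clusters with 1 symbol, 19429 matched a gene of the reference table by gene ID. A gene with more than 1 cluster (769 genes) was represented by the cluster of highest mean, which left 18417 genes. Clusters without a single symbol were named nowhere. Array quartile ranges lay between 3.58 and 3.71 log2 units, except 3.25 on the U266/s melphalan array and 3.34 on the U266/s array with melphalan and inhibitors. The number of arrays limits the precision.

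Models were fitted with limma (version 3.58.1, R 4.3.3) on the log2 values, using empirical Bayes variances with an intensity trend and Benjamini-Hochberg adjustment at 0.05. The additive fit held line, melphalan and inhibitors and left 4 residual degrees of freedom, so its residual spread contains the interactions as well as array error. Interactions were tested by adding 1 term (3 residual degrees of freedom), and the response within each line came from these fits as 2 arrays against 2. Nothing in the labels says whether arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Median residual SD was 0.189 in the additive fit and 0.139 with the melphalan by line term.

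Before the data were examined, 26 gene lists with 791 members were written, of which 721 members were measured. The lists cover p53 targets, replication histones, immediate early genes, G1/S and replication, G2/M and mitosis, crosslink repair, glutathione and NRF2, drug transport, miR-221/222 targets, the BCL2 family, the unfolded protein response, interferon response, NF-kB targets, IL6 and STAT3, plasma cell, adhesion, cholesterol synthesis, heat shock, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins and ribosome biogenesis. Markers of B cells, T and NK cells, myeloid cells, and stromal and epithelial cells completed them. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. Camera at an estimated correlation called 0 lists in every contrast, also where that correlation lay below the preset. A call lost there hence does not show that correlation between genes had made it. Differences between single arrays carry no p, and a list's median was then placed among 10000 random lists matched on mean signal in 20 bins.

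The rule for named genes was also fixed beforehand. It takes the 10 largest called rises and falls of each main effect that run the same way in all 4 matched pairs, or the 5 largest where too few passed. It adds the 5 largest each way within a line or for an interaction, or the 3 largest where none passed. It further takes the 4 members with the largest absolute fold of each list described, and always a fixed set that includes CDKN1A, CDKN1B, CDKN1C, BBC3, BMF, KIT, ABCC1, ABCB1, SLC7A5, MIR221 and MIR222. Y-linked genes and XIST were left out of it.

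On simulated arrays with 18417 genes, changes of 1 log2 unit were recovered in 85% of the altered genes for the line effect, 87% for melphalan, 82% for the inhibitors and 77% for the melphalan by line interaction. For melphalan within U266/s and U266/LR7 the shares were 98% and 99%, and for the inhibitors within these lines 41% and 42%. Changes of 2 log2 units within a line were recovered in 96% and 94% for the inhibitors. The simulated noise was drawn from moderated variances, independently between genes. The line, melphalan and inhibitor simulations held no melphalan by line difference, unlike the real arrays. The recovered shares may thus be too high for the data. There, inhibitor folds over 1 log2 unit, such as EVI2B at 1.16 ± 0.23, did not pass. Of the unaltered genes, 16 were called for the line effect, 19 for melphalan, 10 for the inhibitors and 10 for the interaction. In U266/s and U266/LR7, such false calls numbered 8 and 15 for melphalan and 12 and 13 for the inhibitors.

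Alternatives fixed beforehand were per-array median centring, a filter on dim genes, the mean of a gene's clusters, variances without the trend, omission of each array, all two-way interactions in the model, a 2-fold minimum, and transfection as the 3 levels of the tags. Quantile and cyclic loess normalization of the gene table, the melphalan by line term in the main-effect fits, line differences on arrays without melphalan, and list tests within each line were added after seeing the data. Genomic spans came from a RefSeq table of assembly GRCh38.p14, used for gene length and gene order only. Tables were prepared and plotted with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.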

Results

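RNA of the myeloma lines U266/s and U266/LR7 was profiled 12 h after melphalan, miR-221/222 inhibitors, both or neither, with 1 array per condition and 8 arrays in all. No condition was replicated, so errors come from models that share all arrays. The arrays of the lines correlated at 0.909 to 0.933 over 18417 genes, against 0.986 to 0.996 within U266/LR7 and 0.939 to 0.994 within U266/s. Each array resembled most the array of the same line and melphalan state. The first 3 principal components held 60.3%, 27.5% and 5.44% of the variance.

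The genes with the largest differences between the resistant and the parental line included CCR2, ANXA1 and FGFR3. CCR2, a chemokine receptor, was higher in U266/LR7 by 6.57 ± 0.16 log2 units (SE). Its means were 11.75 ± 0.12 against 5.18 ± 0.25 (SD, n = 4 arrays under 4 different treatments). ANXA1, encoding the phospholipid-binding annexin A1, was lower by -6.49 ± 0.27, and FGFR3, a growth factor receptor, by -5.83 ± 0.14. All 3 changed the same way in 4 of 4 matched pairs, with limma adjusted p of 1.57e-06, 1.08e-05 and 1.57e-06. Other genes higher in U266/LR7 were GPR171 (5.28), SH2D1A (5.03), PSD3 (4.97), ZNF729 (4.93), CD52 (4.80), BRDT (4.76), BPIFC (4.50), LIPH (4.48) and ZNF676 (4.46). Lower genes were APP (-5.65), IQGAP2 (-5.53), HGF (-5.47), DSG2 (-5.31), FRZB (-5.31), CERS6 (-4.79), SLC38A5 (-4.77) and GUCY1A1 (-4.63). In U266/LR7 without melphalan, ANXA1, APP, IQGAP2, HGF, DSG2, FRZB, CERS6 and GUCY1A1 lay under the lower quartile of the genes tested (5.81). CCR2 likewise had low signal in U266/s. The size and rank of these folds are thus limited by the floor.

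Camera called neither drug transport (2 of 19 higher and 6 lower, adjusted p = 0.595) nor the BCL2 family (2 of 17 higher and 2 lower, adjusted p = 0.934). By fry, the BCL2 family was called lower in U266/LR7 (adjusted p = 0.00935) and drug transport was not called (adjusted p = 0.232). Single genes differed as well. ABCC1, a drug efflux pump, was lower in U266/LR7 by -1.91 ± 0.18 (adjusted p = 0.000302), and SLC7A5, a subunit of an amino acid transporter that carries melphalan, by -1.65 ± 0.24 (adjusted p = 0.00173). PMAIP1, which encodes the BH3-only protein NOXA, was lower by -4.42 ± 0.14 (adjusted p = 4.31e-06), and MGST1, a microsomal glutathione transferase, by -4.47 ± 0.35 (adjusted p = 0.000138). GSTM1, a cytosolic glutathione transferase, was higher by 2.98 ± 0.20 (adjusted p = 8.38e-05). The cell cycle inhibitor genes CDKN1B and CDKN1C, both known miR-221/222 targets, had folds of -0.74 ± 0.21 (adjusted p = 0.0318) and -0.50 ± 0.16 (adjusted p = 0.0467). BBC3 (-0.48, adjusted p = 0.0286) and KIT (-0.42, adjusted p = 0.0219) were also called, whereas BMF (-0.15), ABCB1 (-0.21), CDKN1A (0.55), MIR221 (-0.12) and MIR222 (-0.98) were not. CDKN1B, CDKN1C, BBC3 and KIT each lost their call without several single arrays. The BMF value averages opposite differences. Without melphalan BMF signal was 7.21 and 7.58 in U266/LR7 against 8.06 and 8.03 in U266/s. With melphalan it was 8.36 and 8.37 against 7.91 and 8.11.

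In all, 6172 of 18417 genes differed between the lines, 3323 higher and 2849 lower in U266/LR7, and 2221 of them by at least 2-fold. None of the 26 lists was called by camera. Among miR-221/222 targets, 6 of 37 measured members were higher and 13 lower (7 and 13 adjusted over the list alone), with PTPRM at -4.11, TRPS1 at -2.13, ESR1 at -1.34 and ETS1 at -1.27, and the list's adjusted p was 0.647. Of 37 interferon response genes, 14 were higher and 3 lower (the same counts adjusted over the list alone), led by MX2 (2.37), MX1 (1.80), OAS2 (1.72) and OAS3 (1.72). Camera did not call this list (adjusted p = 0.107), whereas fry called it higher in U266/LR7 (adjusted p = 0.0157). The count of differing genes was 4105 among genes above the median signal, 9482 with all two-way interactions and 9846 with the melphalan by line term. On arrays without melphalan it was 6397, with 3114 higher and 3283 lower, so the more frequent direction turned.

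In U266/s, CXCL10 and THEMIS had the largest falls with melphalan, and most of the small nuclear RNA genes rose. CXCL10, a chemokine, fell by 4.28 ± 0.17 log2 units, from 9.24 ± 0.19 to 4.96 ± 0.15 (SD, n = 2 arrays, without and with inhibitors). THEMIS, a T cell signalling gene, fell by 3.58 ± 0.16 (limma adjusted p = 4.95e-07 for CXCL10 and 9.38e-07 for THEMIS). PLA2G4A (-3.33), TDO2 (-3.20) and NCK1 (-2.97) fell as well. With melphalan alone and with the combination, CXCL10 was 5.07 and 4.85 and PLA2G4A 4.69 and 4.95. These values lay under the lower quartiles of all clusters on these arrays (5.34 and 5.24). TDO2 (5.11) also did on the array with melphalan alone. The floor thus limits the size of their falls. PYGM, the muscle glycogen phosphorylase gene, rose by 3.45 ± 0.20 (adjusted p = 1.96e-06), followed by SNORD13P1 (3.40), RNU6ATAC (3.12), SNORD12C (2.99) and RPPH1 (2.87). Of 20 small nuclear RNA genes 18 rose, with a median of 1.09, and of 175 small nucleolar RNA genes 87 rose and 11 fell. In U266/LR7 0 small nuclear RNA genes rose and 4 fell (median -0.329). Long noncoding RNA genes rose in U266/s too (191 higher and 19 lower of 632), on arrays with a narrower signal range, so the rise was not particular to small RNAs.

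By list, 28 of 34 G2/M and mitosis genes fell in U266/s and 1 rose (29 and 1 adjusted over the list alone), including ASPM (-2.36), TTK (-2.30), BUB1B (-2.30) and ECT2 (-2.26), and camera gave an adjusted p of 2.63e-11, and adjusted p = 0.654 with an estimated correlation. Of 28 immediate early genes, 20 rose, with NR4A2 at 2.79, FOS at 2.77 and EGR1 at 2.65, whereas MYC fell by 2.47 (20 and 2 adjusted over the list alone; adjusted p = 2.74e-06, and adjusted p = 0.654 with an estimated correlation). Ribosomal protein genes rose in 33 of 55 cases (34 adjusted over the list alone; adjusted p = 3.1e-09, and adjusted p = 0.696 with an estimated correlation), led by RPL32 (1.38), RPL13 (1.23), RPL27 (1.10) and RPS9 (0.96). Crosslink repair genes fell in 19 of 31 cases and rose in 1 (20 and 2 adjusted over the list alone; adjusted p = 0.000327, and adjusted p = 0.654 with an estimated correlation), including REV1 (-1.68), BLM (-1.62), FANCM (-1.51) and ERCC4 (-1.48), and this call was lost among genes above the median signal (adjusted p = 0.253). Heat shock genes fell in 13 of 19 cases (13 adjusted over the list alone; adjusted p = 0.00173, and adjusted p = 0.654 with an estimated correlation), led by HSPA4L (-2.16), HSPH1 (-1.65), HSPA4 (-1.39) and CHORDC1 (-1.25).

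Ribosome biogenesis genes fell in 13 of 27 cases and rose in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.0154, and adjusted p = 0.654 with an estimated correlation), led by UTP20 (-2.30), POLR1B (-1.77), UTP15 (-1.69) and WDR12 (-1.27). This call was lost with quantile and cyclic loess normalization, where 8 fell and 5 rose (median -0.081) and 6 fell and 5 rose (median -0.073). Of 37 miR-221/222 targets 17 fell and 6 rose (17 and 7 adjusted over the list alone; adjusted p = 0.0272, and adjusted p = 0.717 with an estimated correlation), with RB1 at -2.55, PPP2R2A at -2.40 and TNFSF10 at -2.08 but FOS at 2.77. The target call was lost under both normalizations as well and held in 10 of 14 settings. Myeloid markers rose in 7 of 15 cases (8 adjusted over the list alone; adjusted p = 0.002, and adjusted p = 0.654 with an estimated correlation), among them CD68 (1.88), FCER1G (1.88), CD14 (1.47) and MPO (1.20), and this call was lost among genes above the median signal (adjusted p = 0.098). In all, 7984 genes changed in U266/s, 3391 higher and 4593 lower, of which 373 and 1917 by at least 2-fold. The higher share of calls was 42.5%, but 51.3% with median centring and 53.4% with quantile normalization. No list test took account of genomic span. Among protein-coding genes, those that fell had longer spans (median 57.8 kb) than those that rose (11.9 kb). Without the U266/s control array, 4258 genes were called.

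In U266/LR7, H2BC14 and PCDH9 fell with melphalan, and POLR2A and HEXIM1 rose. H2BC14, a histone H2B gene, fell by 2.47 ± 0.15 (adjusted p = 3.25e-05), and PCDH9, a protocadherin gene, by 2.86 ± 0.15 (adjusted p = 1.16e-05). POLR2A, the gene of the largest RNA polymerase II subunit, rose by 1.77 ± 0.14 (adjusted p = 0.000117), and HEXIM1, which inhibits the elongation factor P-TEFb, by 1.63 ± 0.21 (adjusted p = 0.00125). MUC15 (1.91), SLFN5 (1.77) and TNFRSF10D (1.67) rose, and SYT1 (-2.49), TMEM117 (-2.29) and PITPNC1 (-2.03) fell.

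Of 44 replication histone genes 17 fell in U266/LR7 (23 adjusted over the list alone; adjusted p = 9.91e-21, and adjusted p = 0.785 with an estimated correlation), with H2AC20 at -1.78, H4C2 at -1.60 and H1-3 at -1.52 after H2BC14. G2/M and mitosis genes fell in 9 of 34 cases (12 adjusted over the list alone; adjusted p = 2.77e-10, and adjusted p = 0.785 with an estimated correlation), among them PLK1 (-0.97), DLGAP5 (-0.90) and TOP2A (-0.88), while CENPE stood at -0.97 (adjusted p = 0.0541). Immediate early genes rose in 8 of 28 cases (12, with 1 lower, adjusted over the list alone; adjusted p = 4.77e-05, and adjusted p = 0.785 with an estimated correlation), led by JUN (1.17), FOS (1.15), NR4A2 (1.11) and NR4A1 (0.90). Of 28 p53 targets 4 rose (7, with 1 lower, adjusted over the list alone; adjusted p = 0.00353, and adjusted p = 0.785 with an estimated correlation), including XPC (0.67), CDKN1A (0.66) and PLK3 (0.61), with TIGAR at 0.55 (adjusted p = 0.0829). Only 1 p53 target was higher with median centring, quantile or cyclic loess normalization, the list lost its call without the U266/LR7 control (adjusted p = 0.0794), and in U266/s 8 rose and 11 fell (adjusted p = 0.739). G1/S and replication genes rose in 6 of 35 cases (8, with 1 lower, adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.785 with an estimated correlation), led by CCNE2 (0.81), GINS3 (0.78), CDC6 (0.74) and UHRF1 (0.58), and this call was lost without the array with melphalan and inhibitors (adjusted p = 0.274).

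Cholesterol synthesis (1 of 19 members higher, DHCR7 at 0.56) and plasma cell genes (2 of 23 lower, including XBP1 at -0.50) were each called at an adjusted p of 0.0484, and each had an adjusted p of 0.785 with an estimated correlation. The cholesterol synthesis call held in only 3 and the plasma cell call in only 5 of 14 alternative data settings. In all, 1220 genes changed in U266/LR7, 556 higher and 664 lower. The higher share was 45.6%, but 36.3% with median centring, 35.8% with quantile and 30.6% with cyclic loess normalization. Without the U266/LR7 melphalan array 306 genes were called, and without the array with melphalan and inhibitors 250.

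**Figure D1:**
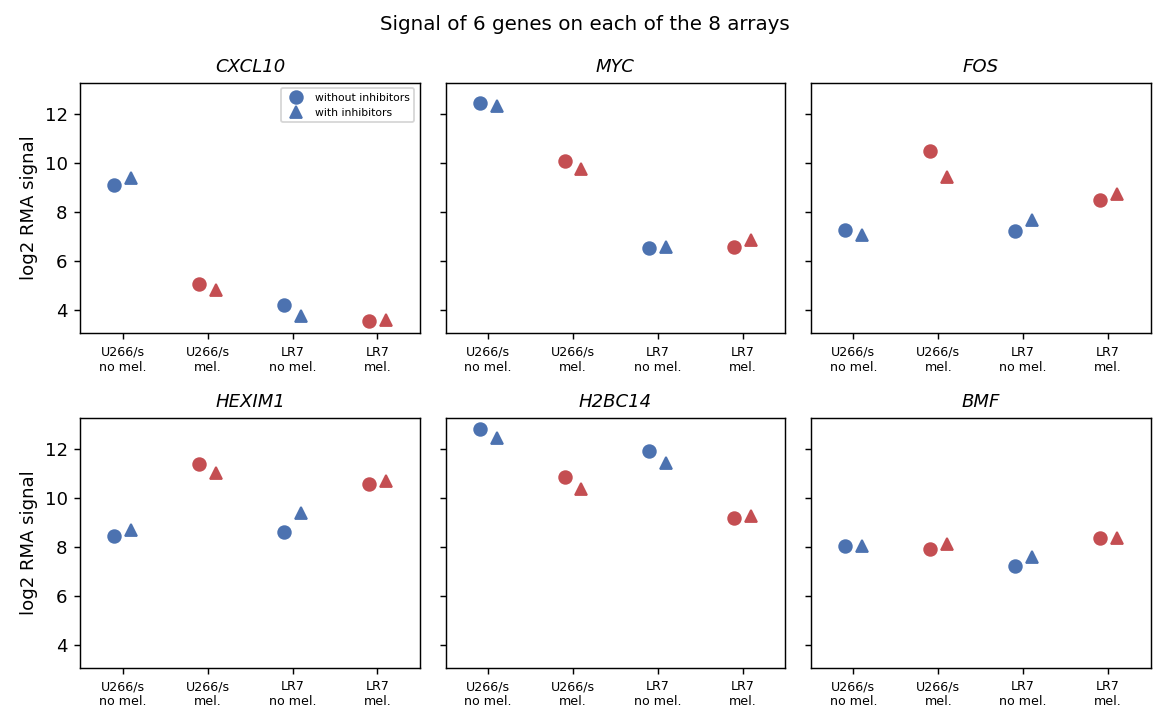
Log2 RMA signal of 6 genes (vertical axis) on each of the 8 arrays, by line and melphalan (horizontal axis; blue without and red with melphalan), with circles for arrays without and triangles for arrays with inhibitors; each point is 1 array and there are no error bars. CXCL10 falls from 9.10 to 5.07 with melphalan alone in U266/s and is at or below 4.22 on all U266/LR7 arrays, whereas HEXIM1 is higher with melphalan on all 4 matched pairs.

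The response differed between the lines for 4394 genes, by the melphalan by line interaction in limma. The interaction was positive for THEMIS (3.90 ± 0.23, adjusted p = 3.4e-05), CXCL10 (3.86), PLA2G4A (3.25), THNSL1 (2.92) and DSG2 (2.90), which means a smaller fall or a larger rise in U266/LR7. It was negative for MTND2P28 (-3.48 ± 0.32, adjusted p = 1e-04), H2AC14 (-3.39), SCARNA9 (-3.37), SNORD13P1 (-3.30) and SNORA49 (-3.07). SLC7A5 fell by 0.38 in U266/s and rose by 0.76 in U266/LR7 (interaction adjusted p = 0.00172), although its fall lost the call under each of the normalizations tried. BMF, a BH3-only gene, rose by 0.97 ± 0.15 in U266/LR7 and stood at -0.03 ± 0.15 in U266/s (interaction adjusted p = 0.00582). CDKN1B fell by 1.07 ± 0.14 in U266/s and stood at -0.12 ± 0.14 in U266/LR7 (interaction adjusted p = 0.00592). THEMIS, CXCL10, PLA2G4A and DSG2 had little room to fall in U266/LR7, where their means without melphalan were 4.41 ± 0.22, 4 ± 0.30, 4.04 ± 0.04 and 3.87 ± 0 (SD, n = 2), under the lower quartile of 5.81, so their terms do not measure a smaller response there.

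Replication histones moved apart between the lines, with 26 of 44 interactions negative and 3 positive (31 and 3 adjusted over the list alone; adjusted p = 3.93e-11, and adjusted p = 0.554 with an estimated correlation). In U266/s 18 histone genes rose and 10 fell, with H2AC14 at 2.69 but H1-5 at -2.86, H2AC21 at -2.08 and H2BC14 at -2.02. Genes called in both lines numbered 165 among higher genes, against 102.4 expected for independent lists, and 465 among lower genes, against 165.6 expected. Over the 7984 genes called in U266/s, folds in the lines had a Pearson r of 0.337 across genes, which are not independent replicates, and 94.68% were smaller in U266/LR7. Choosing genes by their call in U266/s favours a high share. Over all genes r was 0.289. The interaction count was 2552 without the U266/LR7 melphalan array and 2443 without the U266/s control array.

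**Figure D2:**
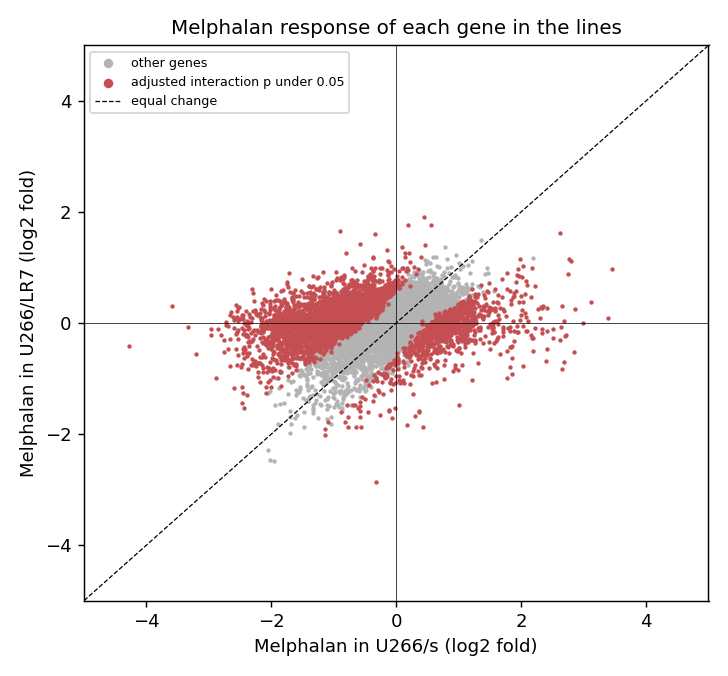
Log2 fold with melphalan in U266/s (horizontal axis) and in U266/LR7 (vertical axis) for 18417 genes, 1 point per gene, with the 4394 genes whose response differed between the lines in red and the dashed line marking equal change. The cloud is wider along the U266/s axis, where 2290 genes changed by at least 2-fold against 256 in U266/LR7.

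Averaged over both lines, melphalan raised HEXIM1 by 2.13 ± 0.25 (adjusted p = 0.0116) and lowered H2BC14 by -2.24 ± 0.15, XRCC4, a DNA end-joining gene, by -1.85 ± 0.12, and SSBP2 by -1.85 ± 0.12 (adjusted p = 0.00268 for each). Higher genes were PYGM (2.21), FOS (1.96), NR4A2 (1.95), SAT1 (1.82), JUN (1.68), CFAP141 (1.58), IDI2 (1.57), SNAI1 (1.53) and EFCAB12 (1.46), and lower genes SYT1 (-2.22), TMEM117 (-2.17), SGMS1 (-1.98), ZSWIM6 (-1.95), ZNF804A (-1.94), PTPN13 (-1.88) and FRYL (-1.86). CDKN1A, the p21 gene and a p53 target, rose by 0.998 ± 0.187 (adjusted p = 0.0345), BBC3, which encodes PUMA, by 0.62 ± 0.13 (adjusted p = 0.0459), and ABCC1 fell by 0.94 ± 0.18 (adjusted p = 0.0373). CDKN1B (-0.59), CDKN1C (0.31), BMF (0.47), KIT (-0.07), ABCB1 (0.05), SLC7A5 (0.19), MIR221 (-0.40) and MIR222 (0.22) were not called.

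This averaged effect gave 838 genes, 253 higher and 585 lower, in an additive fit whose residual holds the strong difference between the lines. The count was 1851 without the U266/LR7 control, 481 without its melphalan array, 31 without its inhibitor array and 37 without its combination array. It was 71, 29, 77 and 43 without the U266/s control, melphalan, inhibitor and combination arrays. With the melphalan by line term it was 6622, and with all two-way interactions 6268. With transfection as 3 levels it was 0, but there the melphalan term rests only on the pairs with inhibitors. That fit also lacks the melphalan by line term, so its 0 does not show that transfection accounts for the effect. Camera called 7 lists, of which G2/M and mitosis (12 of 34 lower, 25 adjusted over the list alone; adjusted p = 6.44e-13), immediate early genes (10 of 28 higher, 18 adjusted over the list alone; adjusted p = 5.28e-06) and ribosomal proteins (0 of 55 called singly; adjusted p = 5.04e-05) held in all 14 alternative data settings. Crosslink repair, adhesion, replication histones and myeloid markers did not, and all 7 had an adjusted p of 0.812 with an estimated correlation.

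The miR-221/222 inhibitors gave 0 genes past the threshold in the additive limma fit, and 375 genes (2.04%) at an unadjusted threshold of 0.05. The residual of that fit holds the melphalan by line difference, and fewer genes passed unadjusted than the threshold alone would give. The test was therefore conservative, and the 0 does not show that the inhibitors had no effect. The largest folds, none of which passed, were SNORD51 (1.22), EVI2B (1.16), RNU4ATAC (1.15), SNORA2A (1.12) and MIR21 (1.06), and AMPD1 (-0.86), ROPN1L (-0.80), TSHR (-0.77), OR2J3 (-0.77) and GMFG (-0.72). Of 37 miR-221/222 targets 0 were called, their median was 0.057 log2 units, and the list's adjusted p was 0.428. CDKN1B stood at -0.19 ± 0.21, CDKN1C at 0.11 ± 0.16, BBC3 at 0.13 ± 0.13, BMF at 0.14 ± 0.22 and KIT at -0.09 ± 0.11. ABCC1 (-0.08), ABCB1 (-0.01), SLC7A5 (0.17), CDKN1A (0.25), MIR221 (0.37) and MIR222 (0.80) were not called either. With the melphalan by line term in the fit 8 genes were called, and with all two-way interactions 20.

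Camera called 5 lists for the inhibitors although 0 of their members passed singly. Hypoxia and glycolysis genes had a median of 0.113 (adjusted p = 5.23e-05, and adjusted p = 0.679 with an estimated correlation) and heat shock genes 0.1 (adjusted p = 0.032, and adjusted p = 0.957 with an estimated correlation). Replication histones (-0.151), ribosomal proteins (-0.088) and plasma cell genes (-0.079) had an adjusted p of 5.23e-05, 1.07e-05 and 0.00639, and an adjusted p of 0.957, 0.957 and 0.679 with an estimated correlation. Only the hypoxia and glycolysis call held in all 14 alternative data settings, and the others held in 10 to 12.

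Within the lines, the inhibitors gave 0 called genes in U266/s (308, or 1.67%, at an unadjusted threshold of 0.05) and 0 in U266/LR7 (212, or 1.15%). These fits hold no melphalan by line term, so that difference stays in their residual. Fewer genes passed unadjusted than the threshold alone would give, so the tests were conservative and could miss real changes. The largest differences in U266/s were MIR222 (1.70 ± 0.22), SNORD51 (1.68) and LINC01356 (1.16). In U266/LR7 they were EVI2B (1.72 ± 0.16, adjusted p = 0.527), MIR21 (1.59) and SLA (1.44). Without inhibitors, MIR222 in U266/s (4.03 and 4.73) lay under the lower quartiles of all clusters there (5.07 and 5.34). EVI2B in U266/LR7 (4.61 and 5.12) lay near or under them (5.14 and 5.09). Both folds thus start near the floor. Whether the MIR221 and MIR222 clusters read the mature microRNAs was not examined. The inhibitor by line and the inhibitor by melphalan interactions gave 0 genes each, with 197 and 134 at an unadjusted threshold of 0.05, under the same limit. Their largest terms were MIR222 (-1.80), SLA (1.47) and SNORD12C (1.43), and SNORD116-1 (1.98), SNORA22 (1.76) and SNORD42A (1.61). The transfection tags leave the inhibitor by melphalan term open to the negative control oligonucleotide.

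Between single arrays, which give values with no replicate check, 102 genes were at least 2-fold higher and 190 lower with melphalan alone in U266/LR7, against 140 and 208 with the combination. In U266/s the numbers were 506 and 2282 for melphalan alone and 432 and 2220 for the combination. Inhibitors alone gave 65 and 34 in U266/LR7, where IL2RB was higher by 1.91 and EVI2B by 1.78. In U266/s they gave 13 and 16, and MIR222 was higher by 2.17. On the control arrays EVI2B (4.61) and MIR222 (4.03) lay under the lower quartiles of all clusters (5.14 and 5.07). The combination differed from melphalan alone by 20 higher and 5 lower genes in U266/LR7, led by SLAMF7 (1.70), and by 22 and 31 in U266/s, led by SNORD51 (2.15). The median of the miR-221/222 targets lay at 0.162 for inhibitors alone in U266/LR7, above 99.55% of 10000 matched random lists, and at 0.019 in U266/s, above 78.3%. The targets did not stand out in U266/LR7, since G2/M and mitosis lay above 99.99%, hypoxia and glycolysis above 99.7% and heat shock above 99.52%, while replication histones and ribosomal proteins lay above 0% of such lists. For the combination against melphalan alone it lay above 25.1% in U266/LR7 and 45.23% in U266/s.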

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

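The tests chosen after the result was seen were the one for U266/LR7 RNA in the U266/s melphalan arrays, the 2 normalizations behind the test of signal range, the planted effects, the count of genes at the floor and the share of U266/LR7 genes with an opposite or larger change. The response to melphalan differed between the lines for 4394 genes, by the interaction term in limma. Genes with a positive term, whose fall was smaller or rise larger in U266/LR7, were THEMIS (3.90), CXCL10 (3.86), PLA2G4A (3.25), THNSL1 (2.92), DSG2 (2.90), NCK1 (2.75), TDO2 (2.65), TNFRSF10D (2.57), HGF (2.38), CERS6 (2.34), GUCY1A1 (2.22), FRZB (2.10), ZNF804A (1.90), IQGAP2 (1.77), APP (1.67), SLFN5 (1.58), MUC15 (1.47) and PTPN13 (1.43). Further such genes were POLR2A (1.21), FRYL (1.20), SLC7A5 (1.14), ANXA1 (1.05), ZSWIM6 (1.03), BMF (0.998), CDKN1B (0.95) and SGMS1 (0.92). THEMIS, CXCL10, PLA2G4A, DSG2, HGF, CERS6, GUCY1A1, FRZB, IQGAP2, APP and ANXA1 lay under the lower quartile of 5.81 in U266/LR7 without melphalan, as did 494 of the 4394 genes (11.2%), so a fall could hardly be seen there.

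Genes with a negative term were MTND2P28 (-3.48), H2AC14 (-3.39), SCARNA9 (-3.37), SNORD13P1 (-3.30), SNORA49 (-3.07), SNORD12C (-2.98), RNU6ATAC (-2.75), RPPH1 (-2.62), PCDH9 (-2.53), PYGM (-2.48), SAT1 (-1.87), NR4A2 (-1.68), FOS (-1.62), CFAP141 (-1.18), CD52 (-1.13), SNAI1 (-1.02) and HEXIM1 (-0.995). The smaller terms were LIPH (-0.99), EFCAB12 (-0.97), PITPNC1 (-0.89), IDI2 (-0.83) and BPIFC (-0.60). By camera, the interaction was positive for crosslink repair (median 0.723), G2/M and mitosis (0.739), heat shock (0.616), ribosome biogenesis (0.473), drug transport (0.31) and G1/S and replication (0.238). It was negative for replication histones (-0.823), immediate early genes (-0.456), myeloid markers (-0.403) and ribosomal proteins (-0.395). All 10 lists lost their call with an estimated correlation. G1/S and replication held in only 9 of 14 alternative data settings, and it and ribosome biogenesis were lost under quantile and cyclic loess normalization, drug transport under cyclic loess.

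For the larger response of U266/s, the narrower signal range of its melphalan arrays was weighed first. After cyclic loess normalization 72.3% of the 4394 genes were called again the same way, and 77.8% after quantile normalization, which argues against the narrower range as the whole cause. U266/LR7 RNA in these arrays is argued against too, since for the median fall of -0.896 it would have to raise the 16 genes over 16-fold higher in U266/LR7 by a median of 3.784, but they changed by 0.189 (95% bootstrap interval -0.30 to 0.378). On the deposited scaling, a single response of smaller size in U266/LR7 was weighed for the genes changed there. Of 1131 above the floor, 30.5% had a called interaction with a fold of opposite sign (258) or a larger change (87) in U266/LR7. The opposite sign need not be a called change in U266/s. The 30.5% was not computed under other normalizations. Choosing genes by their call in U266/LR7 favours opposite or larger changes there, and the interaction holds the same fold. The 30.5% alone therefore decides nothing. Over all genes, 107 called lower and 32 called higher in U266/s were called the other way in U266/LR7. On this scaling, these opposite calls argue against a single smaller response for those genes. For other genes a single response of smaller size stays open, with an r of 0.337 between the lines over all genes called in U266/s. An untested difference in drug response stays open too.

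Other splits of the arrays decide nothing about chance here. The counts were 6172 for the lines and 838 for melphalan, each against at most 0 in the other splits (1 of 33 as large), and 4394 for the interaction against at most 0 (1 of 32). With the real effect planted along each other split, the median count was still 0, because the true effect stays in the residual, so those splits could seldom give as many. For the inhibitors the real count of 0 makes all 33 splits as large, and the highest other, 4264 along the melphalan by line product, points to that structure of the arrays.

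Transcript clusters without a single gene symbol lay outside the comparisons and also moved. Of 13837 such clusters, 4602 (33.3%) changed with melphalan in U266/s, 3650 higher and 952 lower, and 80 changed in U266/LR7. The U266/s melphalan arrays had a narrower signal range. Their lower quartiles were 5.34 and 5.24, against 5.07 and 5.12 without melphalan. Whether the rises reflect this scaling was not tested.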

How the results depend on the processing

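Quantile and cyclic loess normalization, the melphalan by line term in main-effect fits, arrays without melphalan, and the list tests within lines were chosen after seeing the data; the cause of the changes below was not tested unless the setting itself gives it. The line count of 6172 was 4105 above the median signal (fewer genes tested), 9482 with all two-way interactions, 9846 with the melphalan by line term and 2221 with a 2-fold minimum. The melphalan count of 838 was 6268, 6622 and 313 under the last 3 of these settings in the same order, and 29 to 1851 when each array was left out. It was 0 with 3 transfection levels, where only the pairs with inhibitors carry the melphalan term and power is lost. The inhibitor count of 0 was 20 with all two-way interactions and 8 with the melphalan by line term. Omission of each array gave 2443 to 5253 interaction genes, 4258 to 8746 in U266/s (lowest without its control) and 250 to 1472 in U266/LR7. No paired analysis was possible because each condition has 1 array and no replicate number can serve as a block; arrays matched on the other factors were compared within the models.

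Lists called for the line (0) numbered 2 above the median signal, 1 with cyclic loess, 2 by fry and 0 to 7 without each array. For melphalan (7) they numbered 4 above the median signal, 3 with either normalization, 0 with an estimated correlation or fry, and 4 to 8 without each array. For the inhibitors (5) they numbered 9 above the median signal, 0 with an estimated correlation or fry, and 1 to 7 without each array. For the interaction (10) they were 5 above the median signal, 0 with an estimated correlation and 1 by fry. In U266/s (8) they were 4 above the median signal, 0 with an estimated correlation and 15 by fry, and in U266/LR7 (7) 0 with an estimated correlation or fry.

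Of 135 gene values, 19 turned sign somewhere, all of them genes that had not passed the threshold. BMF in U266/s (-0.03) was 0.029 with median centring, 0.215 with quantile, 0.011 with cyclic loess and -0.143 to 0.077 without each array. MIR221 between lines (-0.12) was 0.044 with quantile, 0.012 with cyclic loess and -0.232 to 0.033 without each array. ABCB1 with melphalan (0.05) was -0.02 with quantile, -0.044 with cyclic loess, -0.022 with 3 transfection levels and -0.032 to 0.097 without each array. ABCB1 with the inhibitors (-0.01) was 0.01 with quantile, 0.063 with 3 levels and -0.078 to 0.072 without each array. ABCB1 in U266/s (0.13) was -0.044 with cyclic loess and -0.046 to 0.296 without each array, and in U266/LR7 -0.096 to 0.051. CDKN1C in U266/LR7 (0.04) was -0.029 with cyclic loess and -0.08 to 0.162 without each array. Leaving out each array also gave -0.303 to 0.035 for BMF between lines, -0.162 to 0.028 for KIT and -0.122 to 0.563 for MIR222 with melphalan, and -0.02 to 0.222 for CDKN1C, -0.041 to 0.307 for BMF, -0.224 to 0.032 for ABCC1 and -0.019 to 0.362 for SLC7A5 with the inhibitors. It gave -0.681 to 1.146 for MIR222 in U266/s, and in U266/LR7 -0.282 to 0.046 for CDKN1B, -0.065 to 0.214 for KIT, -0.43 to 0.08 for MIR221 and -0.462 to 0.889 for MIR222. A call was lost in 145 of the comparisons without an array and in 40 under other settings, 23 of these with 3 transfection levels. Signal over background was not used here.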

Other observations

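Here the test on kappa light chain signal, the list tests within lines, and quantile and cyclic loess normalization were chosen after the result was seen. Several further lists were not called by camera with melphalan in U266/s. Of these, fry called adhesion (adjusted p = 0.0242), drug transport (0.0234), the unfolded protein response (0.0235), IL6 and STAT3 (0.0444), NF-kB targets (0.0245), B cell markers (0.0234) and T and NK cell markers (0.0444). Adhesion genes fell in 11 of 29 cases and rose in 2, and drug transport genes fell in 11 of 19 and rose in 2, with camera adjusted p of 0.109 and 0.0729. Of 29 glutathione and NRF2 genes 8 rose and 11 fell, of 30 unfolded protein response genes 4 rose and 11 fell, and of 40 oxidative phosphorylation genes 5 rose and 11 fell, and camera called none of these. With quantile and cyclic loess normalization oxidative phosphorylation turned to 13 higher and 9 lower and to 13 and 5, the unfolded protein response to 9 and 9 and to 8 and 7, and glutathione and NRF2 to 8 and 5 and to 8 and 7. Of 20 IL6 and STAT3 genes 5 rose and 10 fell, of 28 NF-kB targets 5 rose and 6 fell, and of 17 BCL2 family genes 5 rose and 2 fell, again without a call by camera. B cell markers (2 higher and 1 lower of 13), T and NK cell markers (4 higher of 18) and stromal and epithelial markers (1 higher and 2 lower of 16) were not called by camera either. The same held for G1/S and replication (8 higher and 12 lower of 35), cholesterol synthesis (3 and 10 of 19), hypoxia and glycolysis (4 and 11 of 30), the interferon response (7 and 10 of 37) and plasma cell genes (2 and 8 of 23). The excess of falls depended on scaling, since quantile and cyclic loess normalization gave 11 and 9 and 12 and 9 for G1/S and replication, 7 and 7 and 7 and 6 for cholesterol synthesis, 7 and 10 and 9 and 7 for hypoxia and glycolysis, and 5 and 6 and 4 and 5 for plasma cell genes.

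Genes lowered by melphalan had long genomic spans in GRCh38.p14, and over 16899 protein-coding genes the median was 57.8 kb for lower, 11.9 kb for higher and 22.9 kb for uncalled genes in U266/s, and 219.3, 13.9 and 26.5 kb in U266/LR7. Spearman's rho of fold and span, across genes that are not independent, was -0.411 in U266/s and -0.336 in U266/LR7 (95% bootstrap interval -0.351 to -0.322), as a block of transcript elongation by drug adducts, a hypothesis, would predict. The longest genes run against a simple form of it in U266/s, where 34.4% of genes over 300 kb fell (median -0.154) against 46.8% at 100 to 300 kb (median -0.352) and 40.4% at 30 to 100 kb, whereas in U266/LR7 26.6%, 15.2% and 1.19% fell in these bins. Signal level argues little, since the higher rho within signal deciles was -0.327, and the averaged inhibitor effect had a rho of -0.044. That average hides opposite trends, however, with -0.199 for the inhibitors in U266/s and 0.166 in U266/LR7, each over arrays with and without melphalan. Small length trends thus arise in a contrast other than melphalan. Transcript half-life was not tested and stays open. The list tests and the random lists were not matched on span. List calls with melphalan may therefore follow span in part, which was not tested.

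The lines differ in genes that usually mark a myeloma clone. The brightest IGKC cluster, kappa light chain, was lower in U266/LR7 in 4 of 4 pairs, by at least -3.38 log2 units, and 12 of 13 IGKC clusters were lower in all pairs. MYC averaged 6.64 ± 0.15 in U266/LR7 and 11.14 ± 1.43 in U266/s (SD, n = 4 arrays under 4 different treatments), where melphalan itself lowered it. On arrays without melphalan MYC was lower in U266/LR7 by -5.81 ± 0.17 (SE). MYCL was higher in U266/LR7 by 1.20 ± 0.19 (limma adjusted p = 0.00238). U266 is known as a lambda light chain line with little MYC, so the arrays labelled U266/s could stem from another clone, as a hypothesis. On arrays without melphalan, FGFR3 (-5.84), PTPRC (-2.79) and MAF (-2.04) were lower in U266/LR7, and CCND1 was higher by 1.24 ± 0.12 (SE). Averaged over all arrays, CCND1 was high in both lines, at 11.34 and 10.86. The plasma cell genes IRF4 and JCHAIN did not pass the threshold (limma adjusted p = 0.292 and 0.116). As plasma cell genes with high signal in both lines, they cannot tell a shared clone from different clones. A subclone, acquired changes or a label error stay open, and line differences cannot be ascribed to resistance on these data.

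Line differences on arrays without melphalan also ran together along neighbouring genes, with a rank correlation of 0.2 against at most 0.021 in 1000 shuffled orders. Without neighbours that share the first 3 letters of their symbol it was 0.177, above the highest shuffled value of 0.022, so shared family sequence is not the whole cause. Melphalan folds in U266/s gave 0.177 over the same pairs, and copy number differences between the lines therefore cannot be told apart from neighbour effects of other kinds. Both contrasts share the U266/s arrays without melphalan, so the melphalan value is not an independent control. The value of 0.2 met the bound written beforehand for copy number, but that bound was set aside after the melphalan value was seen.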
